A study of Homo sapiens with 24 samples.

How the data were processed

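RNA from 24 cultures or repeats of 2 human osteosarcoma cell lines, U2-OS and SJSA-1, was measured on Affymetrix GeneChip PrimeView arrays. Each line was treated with DMSO or with THZ2 at 25, 100 or 400 nM for 6 h, with 3 arrays per group, per the labels. The treatment protocol names TRIzol for the extraction from these cells, whereas the extraction protocol in the labels names a kit and another tissue. The sources used here do not settle which applies, so marker lists of nervous tissue, blood and epithelium were added, with their levels.

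The deposited values are intensity on a linear scale, 1 per probe set and array. Per the submitters' processing notes the authors used MAS5 and RMA, without saying which made these values, and no versions are given in the sources used here. The values were checked for shared normalization. Within the 9 U2-OS arrays with DMSO, 25 or 100 nM, within the 3 U2-OS arrays with 400 nM, and within the 12 SJSA-1 arrays, some probe sets held exactly the same value in pairs of arrays. Across these 3 sets next to none did, so they were taken as normalized apart. In the SJSA-1 set all values were whole hundredths on the log2 scale, which alone makes identical values, so that they form 1 normalization run is assumed. The SJSA-1 values had thus been on a log2 scale before they were deposited as linear ones.

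Of 49372 probe sets 79 were controls, 44994 named 1 gene, 1832 named several and 2473 other probe sets named none. Only those naming 1 gene were used, and symbols were compared with a RefSeq table of GRCh38.p14, which held 44967 of them and changed none. Coordinates of that table were used only to find the host genes of small RNAs. The values were transformed as log2 of the value plus 16, so that a log2 change of a dim gene depends on the 16 added. A gene was represented by its probe set with the highest mean over all arrays. Genes whose highest group mean lay under the 30th percentile of all deposited values, an intensity of 12.73, were left out, which left 16170 of 18132 genes. Where a group of a named gene lay under that intensity, a lower bound of the fold was computed from the mean of the brighter group and the mean of the dimmer one with each array set to at least that intensity.

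A linear model with 8 group means and 16 residual degrees of freedom was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. There were 14 contrasts: each dose against DMSO within each line, the steps from 25 to 100 and from 100 to 400 nM, the difference between the lines in the effect of each dose, and the DMSO groups of the lines. p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. An exact permutation test on 3 against 3 arrays cannot give a two-sided p below 0.1, so the model across genes was used. No block for the replicate number was used in the model.

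The 26 gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 156 pairs of list and THZ2 comparison, and with an estimated correlation. They cover CTD kinases and partners, immediate early genes, antiapoptotic genes, the proapoptotic BCL2 family, p53 target genes, homologous recombination and checkpoint, the osteoblast lineage, the heat shock response, histones, ribosomal proteins, oxidative phosphorylation, ribosome biogenesis, S phase genes, mitotic genes, NF-kB target genes, ATF4 target genes, YAP and TEAD target genes, TGF-beta and BMP target genes, oncogenes and receptors of osteosarcoma, splicing factors, cholesterol synthesis, interferon genes, nervous tissue, blood and immune and epithelial markers, and KRAB-type zinc finger genes. Members of the last list were not checked for a KRAB domain. The lists, contrasts, model and naming rule were fixed before the data were examined. Line differences per list were tested over 78 pairs of list and dose.

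Genes were named by this rule. The 12 fixed genes are CDK7, CCNH, MNAT1, CDK12, CDK13, POLR2A, MYC, RUNX2, MCL1, MDM2, CDK4 and CDKN1A. For each dose against DMSO the 8 largest falls and 8 largest rises were eligible among genes that passed and whose 3 treated arrays all lay outside the range of the DMSO arrays. From each list up to 3 members in the main direction and 1 in the other were eligible, and for the other contrasts the 6 largest in each direction. The text names a part of the eligible genes, and leaves out those whose direction turned with another choice of probe set where it could. Small nucleolar RNAs among the largest rises were followed up as a set chosen after the values were seen.

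Alternatives tried were arrays centred on their median, on the poly-A spike-ins or on the ribosomal protein genes, quantile normalization, no filter and a filter at the 50th percentile, the mean of a gene's probe sets and each probe set by itself, pseudocounts of 1 and 64, no intensity trend, the replicate number as a block, only the groups of a comparison, fry in place of camera, an estimated correlation, and leaving out each array. No pseudocount and a fit to 1 normalization run were added after the data were examined. For the closing section, counts were compared with other splits of the arrays, and list medians with 10000 random lists of equal size and like intensity. NF-kB target genes were retested with all arrays quantile normalized together. The procedure was tested on simulated data of 16170 genes with known changes. For the contrast of 100 nM with DMSO it recovered 91.0% of changes of 0.5 log2 in U2-OS and 89.6% in SJSA-1, and all of those of 1 or 2 log2. Of 15940 genes without a change it called 20 in U2-OS and 108 in SJSA-1. The median correlation of an array with its own group ran from 0.992 to 0.999. No array was left out.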

Results

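The 24 PrimeView arrays read each transcript with 1 or more probe sets. U2-OS and SJSA-1, both established human osteosarcoma lines, received DMSO, the solvent control, or THZ2 at 25, 100 or 400 nM for 6 h. THZ2 is a covalent inhibitor of CDK7, the kinase of the general transcription factor TFIIH that phosphorylates RNA polymerase II and activates other cyclin-dependent kinases. Each of the 8 groups held 3 arrays, and the labels do not say whether these were separate cultures or repeats of 1 culture. In what follows ± is the standard error of a log2 change from the limma model, or the SD of an intensity, each with n = 3 arrays per group, and "rose" and "fell" are used for genes that passed the adjusted threshold. The number of arrays limits the precision of every value.

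The median intensity per array ran from 33.5 to 34.5 in the 9 U2-OS arrays with DMSO, 25 or 100 nM, from 36.6 to 37.3 in the 3 U2-OS arrays with 400 nM, and from 23.4 to 25.5 in the 12 SJSA-1 arrays. These are taken as 3 sets normalized apart. Between 1.67% and 5.47% of probe sets held exactly the same value in any pair of the 9 arrays, against at most 0.00406% between those arrays and the 400 nM arrays. The SJSA-1 values, and no others, had been rounded to hundredths on the log2 scale, so identical values among them do not show that they were normalized together. In U2-OS the 400 nM dose and its normalization set cannot be told apart, and the same holds for any level compared between the lines. Differences between the lines in the effect of 25 or 100 nM are differences of effects measured within such a set.

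The sources used here do not say whether a change in total RNA per cell would show. The poly-A spike-in transcripts, added to each RNA sample before labelling, were higher than with DMSO by 0.38 (log2) at 100 nM in U2-OS and by 0.45 in SJSA-1. Centring the arrays on these spike-ins moved the median log2 change of all genes at 100 nM from 0.058 to -0.32 in U2-OS and from 0.057 to -0.40 in SJSA-1. At 400 nM it moved the median from 0.15 to -0.18 in U2-OS and from 0.10 to -0.86 in SJSA-1. Centring each array on its own median moved the median change at 100 nM to 0.18 in U2-OS and 0.24 in SJSA-1, and at 400 nM in SJSA-1 to 0.30. Nor is it said whether the amount of spike-in was fixed per mass of RNA or per cell. The other 2 scalings tried were joint quantile normalization and centring on ribosomal protein genes. Changes below are on the deposited scaling unless another is named.

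**Figure D1:**
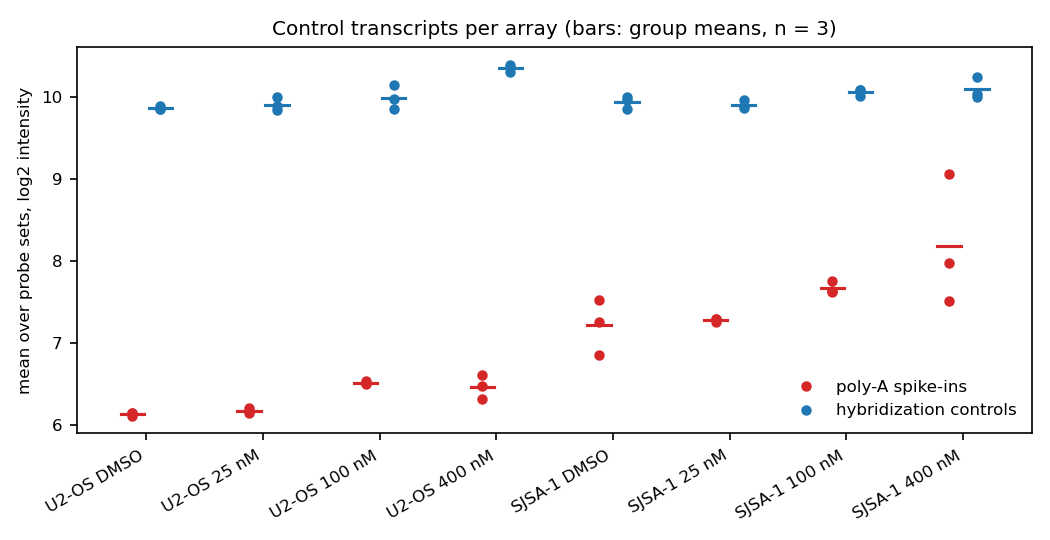
Mean log2 intensity of the poly-A spike-ins and of the hybridization controls (vertical axis) in each array (points) of the 8 groups (horizontal axis), with group means as bars and n = 3 arrays per group. The spike-ins lie 0.38 above DMSO at 100 nM in U2-OS and 0.45 above it in SJSA-1, and SJSA-1 400 nM replicate 2 stands apart at 9.06.

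In SJSA-1, 100 nM THZ2 was compared with DMSO over 6 h within the SJSA-1 set, which cannot tie changes to CDK7 itself. FADD, the adaptor that links death receptors to caspase 8, changed by -3.62 ± 0.14, the largest fall on the scale used, log2 of the intensity plus 16, from an intensity of 1202 ± 158 to 84.9 ± 25.8. ZC3H4, a zinc finger protein that restrains noncoding transcription, changed by -3.15 ± 0.089, from 246 ± 15.3 to 13.6 ± 2.77, a larger ratio of intensities than that of FADD. The transposon-derived ZBED5 changed by -2.89 ± 0.12 and NABP1, a single-stranded DNA binding protein, by -2.79 ± 0.089. The spindle gene KNSTRN changed by -2.79 ± 0.083, the helicase gene DHX32 by -2.70 ± 0.099, the transcriptional coregulator ZMIZ1 by -2.70 ± 0.088 and the microtubule crosslinker MTCL1 by -2.69 ± 0.10. The largest rise on this scale was that of SNORA65, a small nucleolar RNA, at 3.40 ± 0.15. Whether such probe sets read the mature RNA was not tested. SNORA84 rose by 2.37 ± 0.11, SNORA74A by 1.98 ± 0.081, the Cajal body RNA SCARNA14 by 1.91 ± 0.11 and SNHG17, a host gene of small nucleolar RNAs, by 1.95 ± 0.10. C11orf96 rose by 2.90 ± 0.079, the splicing-related RSRP1 by 2.38 ± 0.12 and SAT1, the rate-limiting enzyme of polyamine breakdown, by 2.36 ± 0.077.

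CDK7 itself fell by 0.97 ± 0.10 in SJSA-1 at 100 nM (limma adjusted p = 4.42e-09), while its partners CCNH and MNAT1 did not pass at 0.18 ± 0.11 and 0.097 ± 0.087. The elongation kinase genes CDK12 and CDK13 changed by -0.61 ± 0.095 and -0.90 ± 0.098. POLR2A, which encodes the largest subunit of RNA polymerase II, rose by 0.59 ± 0.11. MYC rose by 0.95 ± 0.10, from an intensity of 33.5 ± 4.28 to 79.5 ± 6.93. RUNX2, a transcription factor of the bone lineage, changed by -1.14 ± 0.14. The antiapoptotic gene MCL1 changed by -1.35 ± 0.14, a fall seen in 5 of its 6 probe sets while 1 went the other way. MDM2 changed by -0.68 ± 0.18 and CDK4 by -0.24 ± 0.059, both genes of the amplified region that SJSA-1 carries. CDKN1A did not pass at -0.023 ± 0.11.

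**Figure D2:**
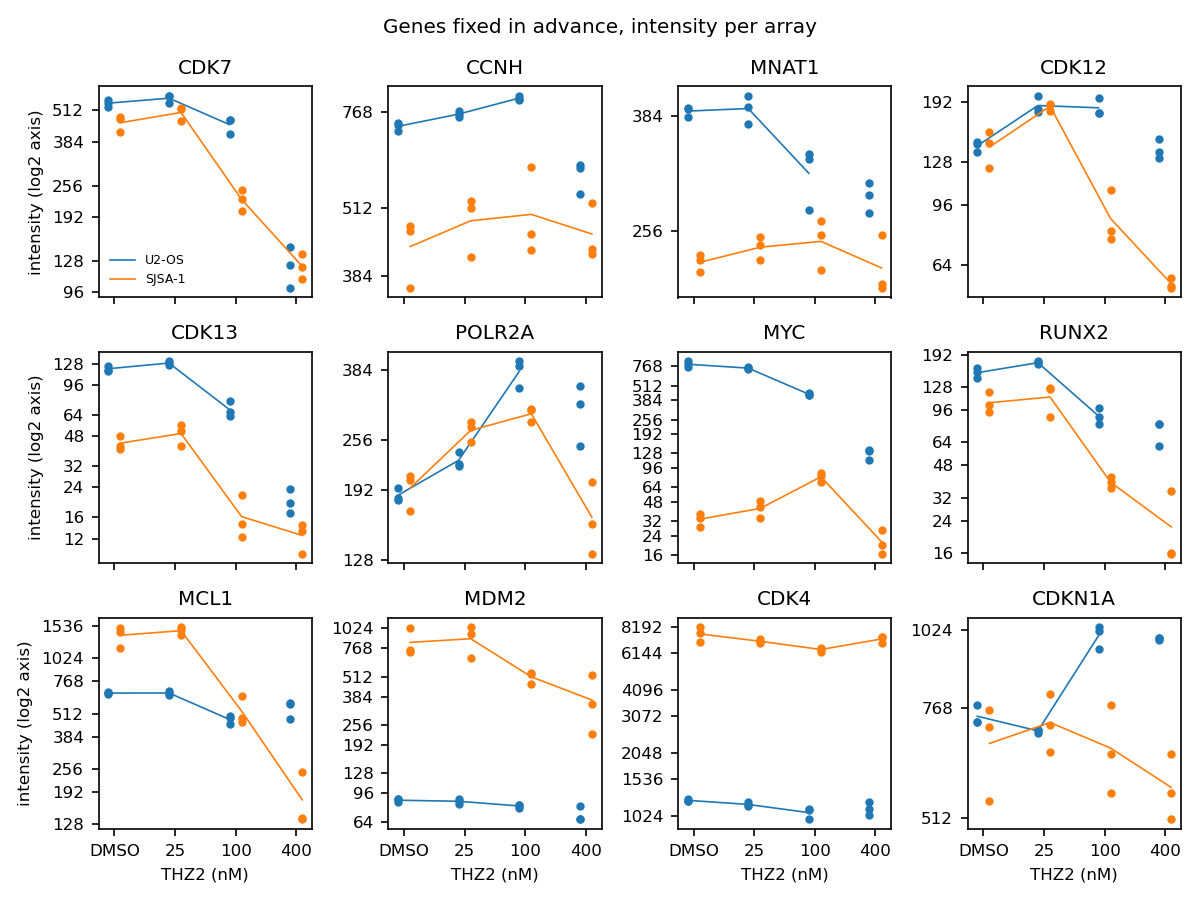
Intensity on a log2 axis of the 12 genes fixed in advance in each array (points) by THZ2 dose, in U2-OS (blue) and SJSA-1 (orange), with lines through the group means of 1 set. MYC lies at 792 ± 48.4 in U2-OS and 33.5 ± 4.28 in SJSA-1 with DMSO.

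Of 16170 genes tested, 7990 changed in SJSA-1 at 100 nM, of which 3955 rose and 4035 fell. By at least 2-fold, which here and below is of the intensity plus 16, 72 rose and 972 fell. These 1044 genes became 1573 (124 up, 1449 down) with no pseudocount, 425 (29 up, 396 down) with a pseudocount of 64, 570 (42 up, 528 down) with the mean of a gene's probe sets and 2302 (27 up, 2275 down) with spike-in centring. With arrays centred on their median the split was 10226 risen and 3044 fallen, with ribosomal centring it was 2649 and 4306, and with spike-in centring it was 53 and 4112. The even split between rises and falls therefore holds only for some scalings. Falls of at least 2-fold outnumbered such rises in each of these fits, while their number depends on the pseudocount, the choice of probe set and the scaling.

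**Figure D3:**
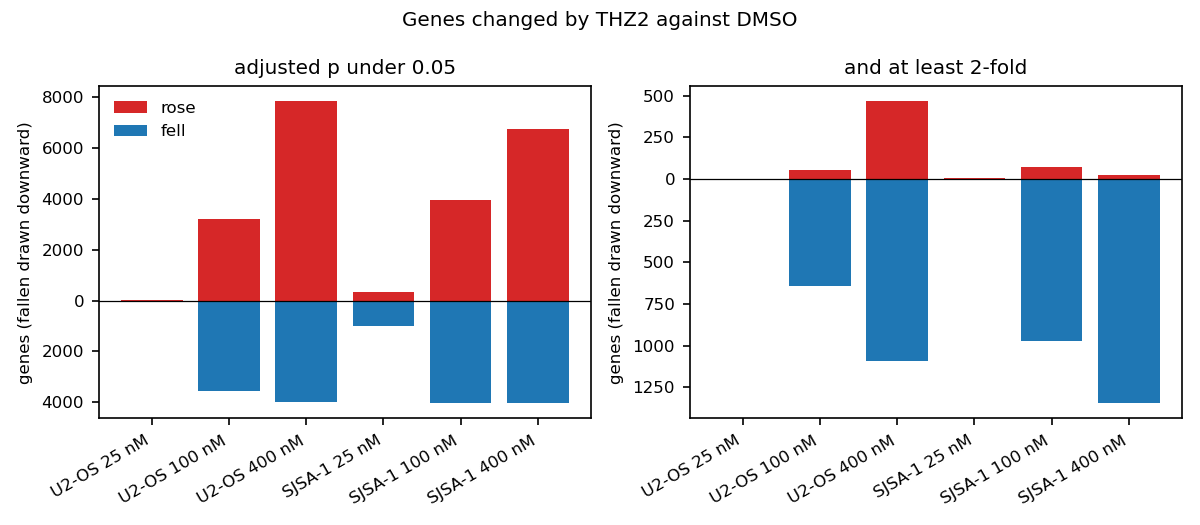
Number of genes (vertical axis, fallen genes drawn downward) with limma adjusted p under 0.05 in each comparison of THZ2 with DMSO, in all and by at least 2-fold. In SJSA-1 at 100 nM 3955 rose and 4035 fell, 72 and 972 by at least 2-fold of the intensity plus 16. Spike-in centring gave 53 and 4112, median centring 10226 and 3044.

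The gene lists were tested in the same comparison with limma. 22 of 29 mitotic genes fell and 0 rose (the same adjusted over the list alone), with camera adjusted p = 1.06e-08 and adjusted p = 0.112 with an estimated correlation. CENPA, the histone variant of centromeres, changed by -2.46 ± 0.10 and the spindle kinesin KIF11 by -1.48 ± 0.13. 16 of 33 S phase genes fell and 2 rose (the same adjusted over the list alone), with camera adjusted p = 5.60e-04 and adjusted p = 0.293 with an estimated correlation. CDC6 changed by -2.29 ± 0.081 and RFC4 by -2.18 ± 0.090. 16 of 27 homologous recombination and checkpoint genes fell and 3 rose (the same adjusted over the list alone), with camera adjusted p = 0.00297 and adjusted p = 0.368 with an estimated correlation. The helicase gene BLM changed by -1.85 ± 0.10 and PALB2 by -1.57 ± 0.10. 182 of 374 KRAB-type zinc finger genes fell and 25 rose (the same adjusted over the list alone), with camera adjusted p = 4.09e-07 and adjusted p = 0.0157 with an estimated correlation, and the median of -0.15 turned positive with median centring. ZNF232 changed by -2.41 ± 0.082 and ZNF827 by -2.13 ± 0.096, KRAB domains unchecked. 15 of 33 ribosome biogenesis genes fell and 3 rose (the same adjusted over the list alone), with camera adjusted p = 0.00331 and adjusted p = 0.358 with an estimated correlation, and the median of -0.17 turned positive with median centring. PPAN changed by -2.04 ± 0.11 and BYSL by -1.08 ± 0.12.

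13 of 24 NF-kB target genes fell and 4 rose (14 and 5 adjusted over the list alone), with camera adjusted p = 0.0216 and adjusted p = 0.481 with an estimated correlation. The NF-kB target call ended with the 50th percentile filter. The inhibitor gene NFKBIE changed by -1.70 ± 0.12, the cytokine gene LIF by -1.68 ± 0.10 and NFKBIZ by -1.18 ± 0.15, while CCL20 rose by 1.11 ± 0.11. 19 of 40 osteosarcoma oncogenes and receptors fell and 8 rose (the same adjusted over the list alone), with camera adjusted p = 0.0314 and adjusted p = 0.467 with an estimated correlation, and the median of -0.13 turned positive with median centring. The oncogene call ended with spike-in or ribosomal centring, the 50th percentile filter or the mean of probe sets, and without DMSO replicate 1 (-0.24). E2F3 changed by -1.93 ± 0.096, and the Notch ligand gene JAG1 rose by 1.42 ± 0.095. 13 of 35 splicing factors fell and 4 rose (the same adjusted over the list alone), with camera adjusted p = 0.0304 and adjusted p = 0.527 with an estimated correlation, and the median of -0.088 turned positive with median centring. The splicing factor call ended with spike-in centring, the 50th percentile filter or the mean of probe sets, and without DMSO replicate 1 (-0.085) or 100 nM replicate 2 (-0.096). RBM39 changed by -1.37 ± 0.12 and SRSF3 by -1.20 ± 0.077. 20 of 28 histone genes rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 1.73e-04 and adjusted p = 0.355 with an estimated correlation, and the median of 0.24 turned negative with spike-in centring. H2AC17 rose by 1.80 ± 0.084 and H2AC8 by 1.69 ± 0.088, although histone genes are near-identical in sequence and their probe sets may read several. 30 of 60 oxidative phosphorylation genes rose and 1 fell (31 and 1 adjusted over the list alone), with camera adjusted p = 3.65e-04 and adjusted p = 0.571 with an estimated correlation, and the median of 0.15 turned negative with spike-in centring. NDUFA12, a subunit of respiratory complex I, rose by 0.40 ± 0.061, which became -0.055 with spike-in centring.

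Lists without a called shift in SJSA-1 at 100 nM often moved in both directions. Of 37 immediate early genes 17 rose and 11 fell, with EGR1 at 1.49 ± 0.11 and FOSL1 at -2.56 ± 0.13 (adjusted over the list alone 17 and 11). Among 23 ATF4 target genes 7 rose and 10 fell, or 7 and 11 adjusted over the list alone, with XBP1 at -2.07 ± 0.11. Of 23 genes of the CTD kinases and their partners 6 rose and 8 fell, or 6 and 9 adjusted over the list alone, with the Mediator kinase module gene MED13 at -2.03 ± 0.12. The 24 interferon genes gave 6 rises and 6 falls, the same adjusted over the list alone, with IRF1 at -1.33 ± 0.12. The 11 antiapoptotic genes gave 6 falls and no rise, the same adjusted over the list alone, with XIAP at -0.92 ± 0.13, for which 1 of 5 probe sets went the other way. The 11 genes of the proapoptotic BCL2 family gave 3 rises and 3 falls, and the 16 cholesterol synthesis genes 3 and 5, the same adjusted over each list alone. Of 65 ribosomal protein genes 10 rose, or 0 adjusted over the list alone, and 1 fell, or 1, with a median of 0.037 that turned negative with spike-in and with ribosomal centring.

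At 400 nM in SJSA-1 the question was how far the changes extended with dose. FADD stood at -4.29 ± 0.14, down to an intensity of 46.1 ± 2.38. FBXO5, an inhibitor of the anaphase-promoting complex, changed by -3.75 ± 0.15, the nuclear pore gene NUP153 by -3.70 ± 0.13, ZNF217 by -3.69 ± 0.12 and the amino acid transporter gene SLC38A2 by -3.68 ± 0.11. WEE1, the kinase that restrains CDK1, changed by -3.48 ± 0.12 and EIF1AD by -3.44 ± 0.13, while for RTL6 at -3.44 ± 0.10 1 of 2 probe sets went the other way. SNORA65 rose by 2.65 ± 0.15, SCARNA14 by 1.74 ± 0.11, SNORA30 by 1.56 ± 0.13, SNORA84 by 1.49 ± 0.11, H2AC17 by 1.71 ± 0.084 and H2AC8 by 1.57 ± 0.088. SAT1 at 1.63 ± 0.077 and ING3 at 1.42 ± 0.14 rose as well, each with 1 of 3 probe sets going the other way.

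Among the fixed genes at 400 nM in SJSA-1, MCL1 changed by -2.90 ± 0.14, again with 1 of 6 probe sets opposite, CDK7 by -1.78 ± 0.10, RUNX2 by -1.69 ± 0.14 and MDM2 by -1.22 ± 0.18. CDK12 changed by -1.12 ± 0.095, CDK13 by -1.07 ± 0.098 and MYC by -0.42 ± 0.10, where MYC was at an intensity of 21.1 ± 5.29. CCNH, MNAT1, POLR2A, CDK4 and CDKN1A did not pass, at 0.077, -0.031, -0.24, -0.077 and -0.22. A call appeared for POLR2A without SJSA-1 DMSO replicate 1 (-0.32) or SJSA-1 400 nM replicate 2 (-0.38), for CDKN1A without SJSA-1 DMSO replicate 1 (-0.36) or SJSA-1 400 nM replicate 2 (-0.31) and for CDK4 without SJSA-1 DMSO replicate 1 (-0.14). In all, 10747 genes changed, 6726 up and 4021 down, and 26 rose and 1345 fell by at least 2-fold. The split was 10689 risen and 2993 fallen with median-centred arrays, 3783 and 4582 with ribosomal centring, and 6 and 14894 with spike-in centring. The poly-A spike-ins of the 3 arrays at this dose differed widely, at 7.97, 9.06 and 7.52 on the log2 scale, so spike-in centring is uncertain at this dose.

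List shifts at 400 nM in SJSA-1 were mostly falls. 26 of 29 mitotic genes fell and 0 rose (the same adjusted over the list alone), with camera adjusted p = 7.66e-12 and adjusted p = 0.0499 with an estimated correlation. AURKA changed by -2.85 ± 0.11 and TTK by -2.03 ± 0.16, both mitotic kinases. 25 of 33 ribosome biogenesis genes fell and 0 rose (the same adjusted over the list alone), with camera adjusted p = 2.60e-09 and adjusted p = 0.0678 with an estimated correlation. NOP16 changed by -2.74 ± 0.087 and POLR1B, a subunit of RNA polymerase I, by -2.13 ± 0.093. 24 of 37 immediate early genes fell and 7 rose (the same adjusted over the list alone), with camera adjusted p = 5.95e-07 and adjusted p = 0.214 with an estimated correlation. FOSL1 changed by -3.41 ± 0.13 and the phosphatase genes DUSP5 and DUSP1 by -2.90 ± 0.10 and -2.63 ± 0.11. 190 of 374 KRAB-type zinc finger genes fell and 52 rose (the same adjusted over the list alone), with camera adjusted p = 1.44e-09 and adjusted p = 0.00610 with an estimated correlation, and the median of -0.19 turned positive with median centring. 16 of 27 p53 target genes fell and 5 rose (the same adjusted over the list alone), with camera adjusted p = 5.31e-04 and adjusted p = 0.253 with an estimated correlation. AEN changed by -2.06 ± 0.10 and SESN2 by -1.97 ± 0.11. 14 of 20 TGF-beta and BMP target genes fell and 1 rose (the same adjusted over the list alone), with camera adjusted p = 5.28e-05 and adjusted p = 0.257 with an estimated correlation. TGIF1 changed by -2.54 ± 0.097 and BAMBI by -2.51 ± 0.095. 13 of 22 YAP and TEAD target genes fell and 2 rose (the same adjusted over the list alone), with camera adjusted p = 7.72e-05 and adjusted p = 0.257 with an estimated correlation. CCN1 changed by -2.60 ± 0.097. 21 of 40 osteosarcoma oncogenes and receptors fell and 6 rose (21 and 7 adjusted over the list alone), with camera adjusted p = 3.10e-04 and adjusted p = 0.237 with an estimated correlation. 20 of 35 splicing factors fell and 5 rose (the same adjusted over the list alone), with camera adjusted p = 8.48e-05 and adjusted p = 0.257 with an estimated correlation. CLK1 changed by -2.04 ± 0.12.

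16 of 33 S phase genes fell and 2 rose (the same adjusted over the list alone), with camera adjusted p = 1.78e-04 and adjusted p = 0.272 with an estimated correlation, and the median of -0.12 turned positive with median centring. GINS3 changed by -2.44 ± 0.11 and CCNE1 by -2.33 ± 0.13. 9 of 17 heat shock response genes fell and 2 rose (the same adjusted over the list alone), with camera adjusted p = 0.0104 and adjusted p = 0.214 with an estimated correlation. DNAJB1, a co-chaperone of HSP70, changed by -3.22 ± 0.12 and HSPA8 by -1.55 ± 0.068. 12 of 23 ATF4 target genes fell and 7 rose (the same adjusted over the list alone), with camera adjusted p = 0.0173 and adjusted p = 0.358 with an estimated correlation. The ATF4 target call ended with the 50th percentile filter. XBP1 changed by -3.14 ± 0.11 and CEBPB by -2.44 ± 0.11. 11 of 23 genes of CTD kinases and their partners fell and 4 rose (the same adjusted over the list alone), with camera adjusted p = 0.0216 and adjusted p = 0.481 with an estimated correlation. The CTD kinase call ended with quantile normalization, spike-in centring, the 50th percentile filter or the mean of probe sets. CDK8 changed by -1.19 ± 0.095. 13 of 27 homologous recombination and checkpoint genes fell and 4 rose (13 and 3 adjusted over the list alone), with camera adjusted p = 0.0470 and adjusted p = 0.549 with an estimated correlation, and the median of -0.065 turned positive with median centring. The recombination call ended with spike-in or ribosomal centring, quantile normalization, the 50th percentile filter, the mean of probe sets or no intensity trend, and without DMSO replicate 1 (-0.027), 400 nM replicate 1 (-0.041) or 2 (-0.071). 49 of 60 oxidative phosphorylation genes rose and 1 fell (50 and 1 adjusted over the list alone), with camera adjusted p = 2.48e-05 and adjusted p = 0.527 with an estimated correlation, and the median of 0.26 turned negative with spike-in centring. UQCRB rose by 0.70 ± 0.098, which became -0.27 with spike-in centring. 18 of 28 histone genes rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 0.00335 and adjusted p = 0.505 with an estimated correlation, and the median of 0.32 turned negative with spike-in centring. 24 of 65 ribosomal protein genes rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 0.0351 and adjusted p = 0.571 with an estimated correlation, and the median of 0.080 turned negative with spike-in centring and ribosomal centring. The ribosomal protein call ended with spike-in or ribosomal centring, quantile normalization, no intensity trend, a fit on its groups, no pseudocount or a fit on its set, and without DMSO replicate 2 (0.062) or 400 nM replicate 1 (0.077).

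At 25 nM in SJSA-1 the changes were smaller. ST6GALNAC5 changed by -1.64 ± 0.094, ARHGEF39 by -1.29 ± 0.089 and NABP1 by -1.20 ± 0.089. MOCS3 changed by -1.13 ± 0.093 and ASF1B by -1.11 ± 0.085. LIAT1 changed by -1.002 ± 0.076, CCDC9B by -0.997 ± 0.090 and DET1 by -0.97 ± 0.074. SNORA3B rose by 1.23 ± 0.088, SNORA26 by 0.995 ± 0.13, ADAMTS16 by 1.16 ± 0.085, USP45 by 1.16 ± 0.094, ANKRD36 by 1.004 ± 0.087 and RNF145 by 0.96 ± 0.092. KMT5B at 1.39 ± 0.095 and NDST1 at 0.96 ± 0.11 also rose, but 3 of 5 and 1 of 4 probe sets, respectively, went the other way. Of the fixed genes POLR2A rose by 0.45 ± 0.11, a call that ended without SJSA-1 25 nM replicate 3 (0.42), and CDK12 by 0.37 ± 0.095, a call that ended without SJSA-1 DMSO replicate 3 (0.28). The other 10 did not pass.

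In SJSA-1 at 25 nM 1322 genes changed, 323 up and 999 down, with 5 rises and 6 falls of at least 2-fold, which were 5 and 12 without SJSA-1 DMSO replicate 1. Spike-in centring left 7 genes. A fit on the 6 arrays of the comparison alone gave 543 (117 up, 426 down), and one on the 12 SJSA-1 arrays gave 559 (108 up, 451 down). The median SD of a gene within a group ran from 0.080 to 0.113 in SJSA-1 and from 0.042 to 0.083 in U2-OS, and the model pools these. 6 of 24 NF-kB target genes fell and 0 rose (11 and 1 adjusted over the list alone), with camera adjusted p = 5.60e-04 and adjusted p = 0.272 with an estimated correlation. IL1B changed by -0.63 ± 0.093 and NFKB2 by -0.51 ± 0.094. 4 of 27 homologous recombination and checkpoint genes fell and 1 rose (5 and 1 adjusted over the list alone), with camera adjusted p = 0.0190 and adjusted p = 0.505 with an estimated correlation. The recombination call ended with the 50th percentile filter or the mean of probe sets, and without DMSO replicate 1 (-0.032) or 25 nM replicate 2 (-0.092). 4 of 17 heat shock response genes rose and 0 fell (6 and 0 adjusted over the list alone), with camera adjusted p = 0.00683 and adjusted p = 0.186 with an estimated correlation. 2 of 21 osteoblast lineage genes rose and 1 fell (4 and 1 adjusted over the list alone), with camera adjusted p = 0.0482 and adjusted p = 0.326 with an estimated correlation, and the median of 0.062 turned negative with spike-in centring. The osteoblast call ended with median or ribosomal centring, no filter, the 50th percentile filter, no intensity trend, a fit on its groups, no pseudocount or a fit on its set, and without DMSO replicate 1 (0.061), 3 (0.066) or 25 nM replicate 1 (0.073). 2 of 37 immediate early genes rose and 2 fell (3 and 2 adjusted over the list alone), with camera adjusted p = 0.0470 and adjusted p = 0.571 with an estimated correlation, and the median of 0.067 turned negative with spike-in centring. The immediate early call ended with median or ribosomal centring, a fit on its groups, no pseudocount, a fit on its set or fry, and without DMSO replicate 1 (0.037), 3 (0.076), 25 nM replicate 1 (0.081) or 3 (0.081).

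The dose steps within SJSA-1 were tested directly, without the shared DMSO arrays. From 25 to 100 nM 6726 genes changed, 3006 up and 3720 down, with 32 rises and 739 falls of at least 2-fold. FADD changed by -2.88 ± 0.14, ZBED5 by -2.62 ± 0.12, ZMIZ1 by -2.46 ± 0.088, CENPA by -2.44 ± 0.10, KNSTRN by -2.36 ± 0.083 and ZC3H4 by -2.32 ± 0.089. SNORA65 rose by 2.69 ± 0.15, C11orf96 by 2.11 ± 0.079 and SAT1 by 1.96 ± 0.077. From 100 to 400 nM 4281 genes changed, 2400 up and 1881 down, with 7 rises and 425 falls of at least 2-fold. The Mediator gene MED26 changed by -3.05 ± 0.11, CITED2 by -3.03 ± 0.13, FBXO5 by -2.74 ± 0.15, RND3 by -2.68 ± 0.14, IRF2BPL by -2.68 ± 0.17 and ING1 by -2.62 ± 0.12. MYC, which had risen at 100 nM, changed by -1.37 ± 0.10 over this step, and POLR2A by -0.82 ± 0.11. E2F5 rose by 1.43 ± 0.10, OSGEPL1 by 1.25 ± 0.11, the cytokine gene IL6 by 1.10 ± 0.096 and the TFIIH gene GTF2H1 by 1.09 ± 0.093. The lower step gave 12612 genes (9789 up, 2823 down) with median-centred arrays, 6151 with ribosomal centring (2034 up, 4117 down) and 3295 (26 up, 3269 down) with spike-in centring. The upper step gave 2150 (2 up, 2148 down) with spike-in centring, 3684 with ribosomal centring (1576 up, 2108 down), 2301 (901 up, 1400 down) on the 6 arrays alone and 2685 (1237 up, 1448 down) on the 12 SJSA-1 arrays.

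In U2-OS 25 nM THZ2 changed few genes. EGR1 changed by -0.57 ± 0.11, from an intensity of 255 ± 13.9 to 167 ± 9.11. KRCC1 changed by -0.51 ± 0.077, ASF1B by -0.45 ± 0.085, SSU72 by -0.42 ± 0.080, and XYLT1 by -0.33 ± 0.047. CARD8 rose by 0.50 ± 0.087, CRISPLD1 by 0.39 ± 0.072, ACOX3 by 0.39 ± 0.069 and ZNF552 by 0.29 ± 0.058. None of the 12 fixed genes passed. Yet CDK12 went from 143 to 188 (142 to 187 in SJSA-1) and POLR2A from 186 to 228 (194 to 271). The calls of EGR1, ASF1B, SSU72 and ZNF552 ended whichever of the 6 arrays was left out, with log2 changes from -0.61 to -0.53 for EGR1, and those of ACOX3, CARD8 and CRISPLD1 ended for 5, 4 and 4 of the 6 arrays. By limma 13 genes changed, 4 up and 9 down, none by 2-fold, and 650 had an unadjusted p under 0.05. The count depended on the model. It was 800 (480 up, 320 down) on the 6 arrays alone and 303 (170 up, 133 down) on the 9 arrays of the normalization set, 0 with spike-in centring, and between 4 and 8 when any 1 array was left out.

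Shifts of 6 lists were called in U2-OS at 25 nM although at most 1 member of each passed, so these are shifts of many small values. The camera adjusted p was 0.00867 for CTD kinases and partners (adjusted p = 0.385 with an estimated correlation, median 0.059), 0.0196 for mitotic genes (adjusted p = 0.514 with an estimated correlation, median 0.041) and 0.0218 for cholesterol synthesis genes (adjusted p = 0.292 with an estimated correlation, median 0.072). It was 0.0452 for heat shock genes (adjusted p = 0.273 with an estimated correlation, median 0.051), 0.0452 for ribosome biogenesis genes (adjusted p = 0.527 with an estimated correlation, median 0.030, which turned to -0.010 with spike-in centring) and 0.0262 for immediate early genes (adjusted p = 0.527 with an estimated correlation, median -0.040). Adjusted over the list alone 2 CTD kinase genes rose and 1 immediate early gene fell, and no gene of the other 4 lists passed. The heat shock call ended with quantile normalization, the 50th percentile filter, no intensity trend or fry, and without DMSO replicate 1 (0.048), 3 (0.041), 25 nM replicate 2 (0.043) or 3 (0.043). The ribosome biogenesis call ended with quantile normalization, the 50th percentile filter, the mean of probe sets or fry, and without DMSO replicate 1 (0.028), 3 (0.035), 25 nM replicate 2 (0.030) or 3 (0.020). For immediate early genes the call ended with the mean of probe sets or fry, and without DMSO replicate 1 (-0.037), 2 (-0.058) or 25 nM replicate 2 (-0.033), and for mitotic genes with quantile normalization, the 50th percentile filter or fry, and without 25 nM replicate 2 (0.032) or 3 (0.040). That of the CTD kinases ended with fry and that of cholesterol synthesis with quantile normalization, the 50th percentile filter or fry.

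At 100 nM in U2-OS PMEPA1, a target and inhibitor of TGF-beta signalling, changed by -3.48 ± 0.13, the largest fall on log2 of the intensity plus 16, from an intensity of 1680 ± 52.2 to 136 ± 13.9. ST6GALNAC5 changed by -3.42 ± 0.094, from 674 ± 24.5 to 48.6 ± 3.42, a larger ratio of intensities. ZBED5 changed by -2.83 ± 0.12, ZC3H4 by -2.66 ± 0.089, the insulin receptor substrate gene IRS1 by -2.58 ± 0.092, FRMD6 by -2.51 ± 0.098 and GOPC by -2.51 ± 0.10. For TUBGCP3 at -2.58 ± 0.081 1 of 5 probe sets went the other way. EID3 rose by 2.84 ± 0.095, C11orf96 by 2.38 ± 0.079, SAT1 by 2.34 ± 0.077, SNORA65 by 1.84 ± 0.15 and SHISA2 by 1.83 ± 0.094. The chemokine gene CXCL8 rose by 2.22 ± 0.083, from 78.5 ± 3.01 to 425 ± 31.6, and the kinase gene SGK1 by 1.88 ± 0.14. NFYA rose by 2.69 ± 0.14 on its brightest probe set, but 2 of its 4 probe sets fell.

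CDK7 changed by -0.28 ± 0.10 in U2-OS at 100 nM, a call that ended without U2-OS DMSO replicate 2 (-0.26), 3 (-0.28) or U2-OS 100 nM replicate 1 (-0.22). MNAT1 changed by -0.31 ± 0.087, a call that ended without U2-OS 100 nM replicate 1 (-0.22), and CDK13 by -0.68 ± 0.098. MYC changed by -0.86 ± 0.10, from 792 ± 48.4 to 429 ± 8.76, and CDK4 by -0.19 ± 0.059, a call that ended without U2-OS 100 nM replicate 1 (-0.14). RUNX2 changed by -0.69 ± 0.14 with 1 of 2 probe sets opposite, and MCL1 by -0.46 ± 0.14 with 1 of 6 opposite. POLR2A rose by 0.97 ± 0.11 and CDKN1A by 0.42 ± 0.11, and CDK12 by 0.33 ± 0.095, which became -0.045 with spike-in centring. CCNH and MDM2 did not pass at 0.17 and -0.10. In all 6773 genes changed, 3202 up and 3571 down, and 53 rose and 640 fell by at least 2-fold. The split was 8622 up and 2922 down with median-centred arrays and 45 up and 3031 down with spike-in centring, and the 9 arrays of the normalization set alone gave 10229 (5795 up, 4434 down).

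Lists shifted in U2-OS at 100 nM as follows. 173 of 374 KRAB-type zinc finger genes fell and 36 rose (176 and 37 adjusted over the list alone), with camera adjusted p = 4.69e-08 and adjusted p = 0.0111 with an estimated correlation. ZNF7 changed by -2.23 ± 0.14. 16 of 27 homologous recombination and checkpoint genes fell and 1 rose (the same adjusted over the list alone), with camera adjusted p = 2.48e-05 and adjusted p = 0.253 with an estimated correlation. BARD1 changed by -1.53 ± 0.093 and BRCA1 by -1.32 ± 0.10. 17 of 29 mitotic genes fell and 2 rose (18 and 2 adjusted over the list alone), with camera adjusted p = 3.36e-04 and adjusted p = 0.292 with an estimated correlation. CENPA changed by -1.83 ± 0.10. 12 of 24 NF-kB target genes rose and 3 fell (the same adjusted over the list alone), with camera adjusted p = 9.41e-04 and adjusted p = 0.285 with an estimated correlation, and the median of 0.18 turned negative with spike-in centring. Besides CXCL8, CCL20 rose by 1.79 ± 0.11 and CCL2 by 1.68 ± 0.12, while NFKBIE changed by -0.85 ± 0.12. 18 of 60 oxidative phosphorylation genes rose and 2 fell (17 and 2 adjusted over the list alone), with camera adjusted p = 0.00455 and adjusted p = 0.657 with an estimated correlation, and the median of 0.13 turned negative with spike-in centring. 10 of 22 YAP and TEAD target genes fell and 1 rose (the same adjusted over the list alone), with camera adjusted p = 0.0291 and adjusted p = 0.527 with an estimated correlation, and the median of -0.078 turned positive with median centring. The YAP and TEAD target call ended with spike-in centring, the 50th percentile filter or the mean of probe sets. ASAP1 changed by -1.25 ± 0.11. 10 of 33 S phase genes fell and 2 rose (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0351 and adjusted p = 0.527 with an estimated correlation, and the median of -0.12 turned positive with median centring. The S phase call ended with quantile normalization, spike-in centring, the 50th percentile filter or the mean of probe sets, and without 100 nM replicate 1 (-0.10). GINS1 changed by -1.54 ± 0.077. Of 37 immediate early genes 16 rose and 10 fell with no called shift, or 18 and 10 adjusted over the list alone, with FOSL1 at -2.11 ± 0.13 and ATF3 at 1.36 ± 0.080.

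Between 25 and 100 nM in U2-OS 7757 genes changed, 4016 up and 3741 down, with 38 rises and 628 falls of at least 2-fold. ST6GALNAC5 changed by -3.21 ± 0.094, PMEPA1 by -3.15 ± 0.13, ZBED5 by -2.79 ± 0.12, IRS1 by -2.49 ± 0.092 and YAE1 by -2.42 ± 0.12. EID3 rose by 2.71 ± 0.095, CXCL8 by 2.28 ± 0.083 and SAT1 by 2.20 ± 0.077. With median-centred arrays 11604 genes changed, 8589 up and 3015 down, and with spike-in centring 2889, 36 up and 2853 down.

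The 400 nM arrays of U2-OS belong to their own normalization set, so their differences from the other U2-OS arrays hold the dose and the set together. Probe sets near background spread widely there, with an SD of 0.39 in their log2 difference from DMSO against 0.15 at 100 nM. ZBED5 stood at -3.86 ± 0.12, ST6GALNAC5 at -3.74 ± 0.094, NGDN at -3.60 ± 0.10, the ribosome biogenesis gene NOP16 at -3.37 ± 0.087, PNRC2 at -3.17 ± 0.12 and MPHOSPH10 at -3.14 ± 0.12. IRS1 at -3.50 ± 0.092 and BCL11A at -3.15 ± 0.069 each had 1 probe set going the other way, of 3 and 7. CXCL8 stood at 3.37 ± 0.083, IER3 at 2.91 ± 0.075, CCL2 at 2.62 ± 0.12, CXCL3 at 2.53 ± 0.11, EGR1 at 2.41 ± 0.11, SERPINB7 at 2.40 ± 0.088 and ARC at 2.34 ± 0.13. MYC differed by -2.49 ± 0.10, CDK7 by -2.03 ± 0.10, CDK13 by -1.92 ± 0.098 and POLR2A by 0.65 ± 0.11, whereas MCL1 did not pass at -0.27 ± 0.14.

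In this comparison 11833 genes differed from DMSO, 7829 up and 4004 down, with 467 rises and 1090 falls of at least 2-fold, and with spike-in centring 3501, 461 up and 3040 down. Against 100 nM 10423 genes differed, 7168 up and 3255 down, a split of 5272 and 4699 with quantile normalization and of 1592 and 737 with spike-in centring. GTF2B, a general transcription factor gene, differed by -2.98 ± 0.11 from 100 nM, NGDN by -2.95 ± 0.10, MED26 by -2.77 ± 0.11, PELO by -2.71 ± 0.12 and CENPC by -2.67 ± 0.12. SHOC1 differed by 2.48 ± 0.082, SERPINB7 by 2.40 ± 0.088 and EGR1 by 1.98 ± 0.11.

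The list shifts at 400 nM in U2-OS hold the same confounding. 26 of 33 ribosome biogenesis genes fell and 0 rose (the same adjusted over the list alone), with camera adjusted p = 9.28e-10 and adjusted p = 0.0611 with an estimated correlation. 234 of 374 KRAB-type zinc finger genes fell and 74 rose (234 and 77 adjusted over the list alone), with camera adjusted p = 7.12e-14 and adjusted p = 0.00124 with an estimated correlation. 52 of 60 oxidative phosphorylation genes rose and 1 fell (the same adjusted over the list alone), with camera adjusted p = 2.48e-05 and adjusted p = 0.527 with an estimated correlation. 22 of 35 splicing factors fell and 5 rose (the same adjusted over the list alone), with camera adjusted p = 8.48e-05 and adjusted p = 0.257 with an estimated correlation. SRSF3 differed by -1.68 ± 0.077. 14 of 20 TGF-beta and BMP target genes fell and 3 rose (the same adjusted over the list alone), with camera adjusted p = 1.12e-04 and adjusted p = 0.257 with an estimated correlation. 16 of 29 mitotic genes fell and 6 rose (the same adjusted over the list alone), with camera adjusted p = 3.70e-04 and adjusted p = 0.293 with an estimated correlation. AURKA differed by -2.44 ± 0.11. 12 of 27 homologous recombination and checkpoint genes fell and 5 rose (the same adjusted over the list alone), with camera adjusted p = 0.0139 and adjusted p = 0.483 with an estimated correlation. The recombination call ended with spike-in centring or the mean of probe sets. 12 of 23 ATF4 target genes fell and 6 rose (the same adjusted over the list alone), with camera adjusted p = 0.0139 and adjusted p = 0.355 with an estimated correlation. 17 of 40 osteosarcoma oncogenes and receptors fell and 15 rose (the same adjusted over the list alone), with camera adjusted p = 0.0211 and adjusted p = 0.385 with an estimated correlation. The oncogene call ended with the 50th percentile filter or the mean of probe sets. 6 of 11 antiapoptotic genes fell and 1 rose (the same adjusted over the list alone), with camera adjusted p = 0.0253 and adjusted p = 0.214 with an estimated correlation. The antiapoptotic call ended with the 50th percentile filter. BCL2A1 differed by -2.20 ± 0.089. 11 of 22 YAP and TEAD target genes fell and 5 rose (the same adjusted over the list alone), with camera adjusted p = 0.0314 and adjusted p = 0.527 with an estimated correlation. The YAP and TEAD target call ended with quantile normalization or the 50th percentile filter. FJX1 differed by -2.88 ± 0.12. 8 of 17 heat shock response genes fell and 3 rose (the same adjusted over the list alone), with camera adjusted p = 0.0323 and adjusted p = 0.257 with an estimated correlation. The heat shock call ended with spike-in centring or the 50th percentile filter. 14 of 33 S phase genes fell and 13 rose (15 and 13 adjusted over the list alone), with camera adjusted p = 0.0470 and adjusted p = 0.549 with an estimated correlation. The S phase call ended with quantile normalization, ribosomal centring, the 50th percentile filter, no intensity trend, a fit on its groups or no pseudocount, and without DMSO replicate 2 (-0.20) or 400 nM replicate 1 (-0.13).

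**Figure D4:**
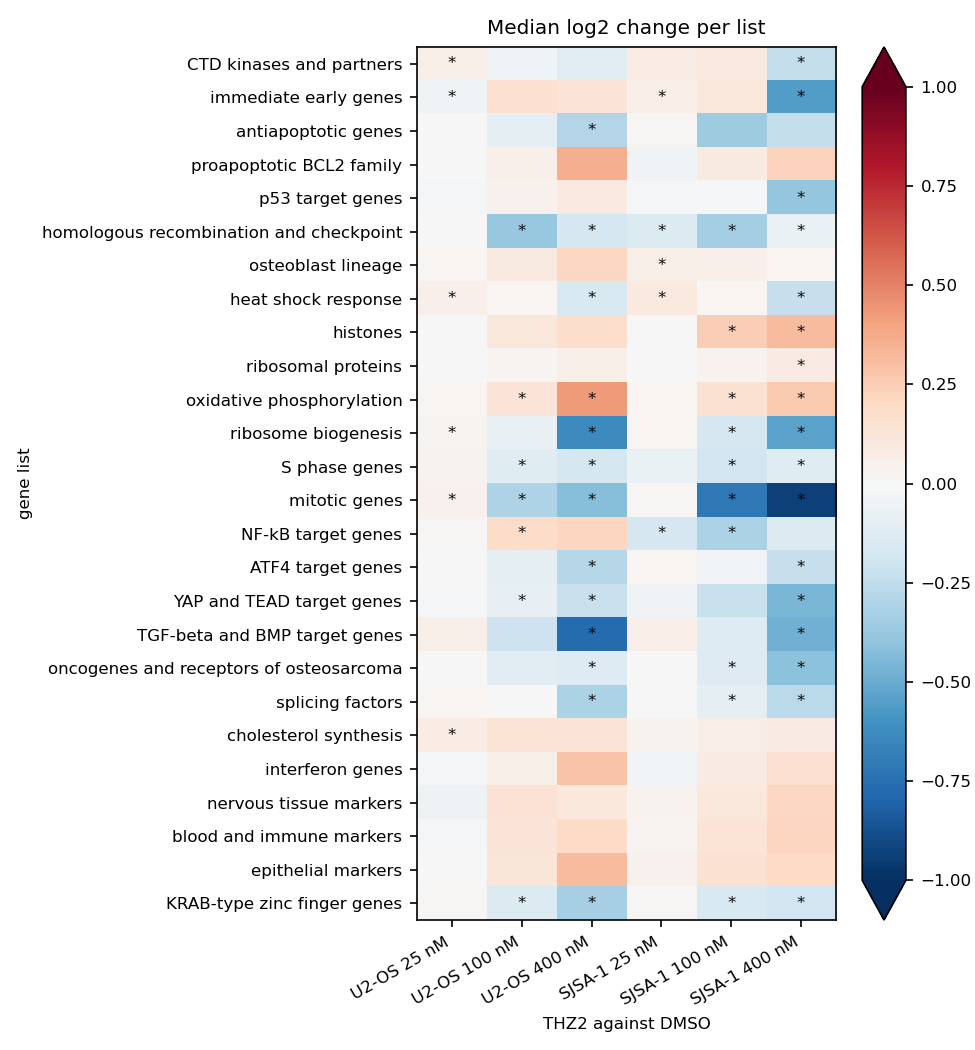
Median log2 change (colour) of the 26 gene lists in the 6 comparisons of THZ2 with DMSO, with a star where the limma camera adjusted p was under 0.05. The mitotic genes have medians of -0.72 and -0.94 in SJSA-1 at 100 and 400 nM, negative with every scaling, while the positive medians of oxidative phosphorylation genes at 100 nM, 0.13 in U2-OS and 0.15 in SJSA-1, turned negative with spike-in centring.

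Whether the lines respond differently was tested as the SJSA-1 effect minus the U2-OS effect at the same dose. At 100 nM CXCL8 gave -2.55 ± 0.12, the RNA-binding protein gene IGF2BP1 -2.43 ± 0.13, NFKBIZ -2.40 ± 0.21 and PHLDA1 -2.39 ± 0.14, all lower in SJSA-1. ST6GALNAC5 gave 2.19 ± 0.13, ZNF518B 1.93 ± 0.12 and MYC 1.81 ± 0.15, all higher in SJSA-1. No value is given for genes under the filter intensity of 12.73 in both groups of a line, BNC1, ZIC5 and H2AC17 in U2-OS and BCL11A and CCDC62 in SJSA-1, since no response can be read there. At 400 nM this holds for DKK1, ZIC2 and TFAP2C in U2-OS and BCL11A and SDR42E1 in SJSA-1. MYC thus fell in U2-OS and rose in SJSA-1 at 100 nM, starting from DMSO intensities of 792 ± 48.4 and 33.5 ± 4.28. CDK12 differed by -0.95 ± 0.13, MCL1 by -0.89 ± 0.20, CDK7 by -0.69 ± 0.14, CDKN1A by -0.44 ± 0.15 and MNAT1 by 0.41 ± 0.12. The MNAT1 call ended without U2-OS 100 nM replicate 1 (0.32) or SJSA-1 100 nM replicate 2 (0.36), and that of CDKN1A for 9 of the 12 arrays, with values from -0.59 to -0.33. The effect differed for 2708 genes, 1147 higher and 1561 lower in SJSA-1, and by at least 2-fold for 61 and 161. The split was 1774 higher and 1249 lower with median-centred arrays, and spike-in centring left 49 genes, 12 higher and 37 lower.

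**Figure D5:**
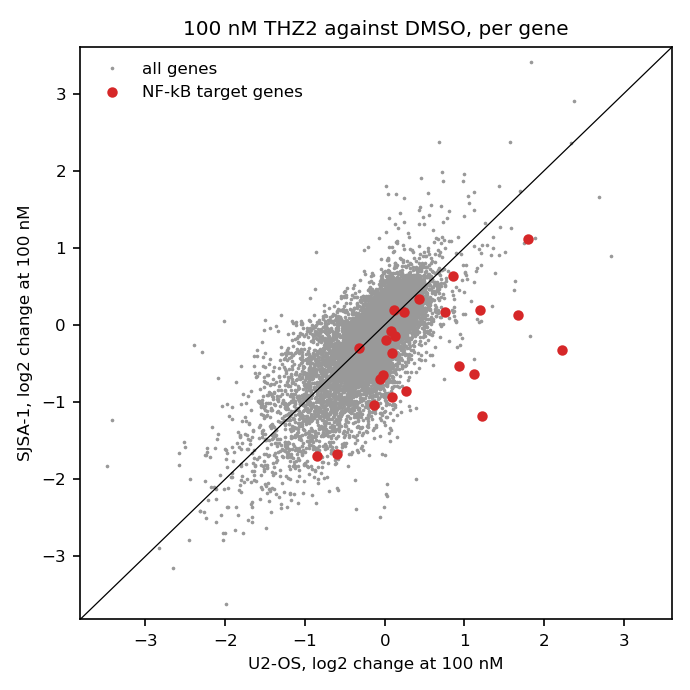
Log2 change at 100 nM THZ2 against DMSO of each of 16170 genes in U2-OS (horizontal axis) and SJSA-1 (vertical axis), with the NF-kB target genes in red and a line of equal change. Over all genes Pearson r is 0.769, and the median difference of the NF-kB target genes, SJSA-1 minus U2-OS, is -0.66.

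Of 24 NF-kB target genes 16 were lower in SJSA-1 and 0 higher in the difference of the 100 nM effect, the same adjusted over the list alone, with a median of -0.66, camera adjusted p = 2.83e-15, and adjusted p = 0.0153 with an estimated correlation. Mitotic genes had 12 of 29 lower and 0 higher, or 13 and 0 adjusted over the list alone (median -0.25, camera adjusted p = 1.14e-04, adjusted p = 0.425 with an estimated correlation). Histone genes had 7 of 28 higher and 2 lower, or 8 and 2 adjusted over the list alone (median 0.14, camera adjusted p = 0.00190, adjusted p = 0.660 with an estimated correlation). For the p53 target genes, with 11 lower and 2 higher, or 14 and 2 adjusted over the list alone, the median was -0.33 (camera adjusted p = 0.0233, adjusted p = 0.646 with an estimated correlation), for S phase genes (8 lower and 1 higher, or 10 and 1 adjusted over the list alone) -0.067 (adjusted p = 0.0233, adjusted p = 0.752 with an estimated correlation) and for splicing factors (8 lower and 0 higher, or 9 and 0 adjusted over the list alone) -0.10 (adjusted p = 0.0397, adjusted p = 0.815 with an estimated correlation). These list differences were tested in addition to the shifts within each line, over 78 pairs of list and dose, and none of the 6 medians changed sign with another scaling. With median centring, however, that of the S phase genes became -0.0017 and that of the splicing factors -0.034.

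At 25 nM the effect differed for 174 genes, 31 higher and 143 lower in SJSA-1. ST6GALNAC5 gave -1.43 ± 0.13, NABP1 -1.07 ± 0.13, LIAT1 -0.95 ± 0.11 and ARHGEF39 -0.92 ± 0.13, and SNORA3B gave 1.17 ± 0.12, SNORA26 1.02 ± 0.19 and USP45 0.97 ± 0.13. The count was 79 without U2-OS 25 nM replicate 3 and 320 without SJSA-1 DMSO replicate 1, and 0 with spike-in centring. The NF-kB target genes had a median difference of -0.21 at 25 nM (camera adjusted p = 2.78e-04, adjusted p = 0.415 with an estimated correlation). At 400 nM, where the U2-OS effect holds its normalization set too, 7385 genes differed, 2329 higher and 5056 lower in SJSA-1. NFKBIZ gave -3.55 ± 0.21, CXCL8 -3.23 ± 0.12 and PHLDA1 -3.18 ± 0.14. ST6GALNAC5 gave 3.17 ± 0.13, SCG5 2.12 ± 0.15 and MYC 2.07 ± 0.15, and MCL1 differed by -2.63 ± 0.20. The split at 400 nM was 4134 higher and 3147 lower with median-centred arrays, 3951 and 3405 with quantile normalization, and 23 and 5143 with spike-in centring.

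In 10 of the results above on THZ2 within a line 1 group lay under the filter intensity of 12.73, so that the log2 change is set in part by the 16 added and only a lower bound of the fold holds. In SJSA-1 at 400 nM WEE1 was at least 20.9-fold, SESN2 at least 6.09-fold and CDK13 at least 3.24-fold lower than with DMSO. At 100 nM ZNF827 was at least 7.23-fold lower and SNORA74A at least 7.02-fold higher, and at 25 nM ST6GALNAC5 was at least 4.53-fold lower and ADAMTS16 at least 3.70-fold higher. In U2-OS KRCC1 was at least 1.45-fold lower at 25 nM, SHISA2 at least 6.24-fold higher at 100 nM and CXCL3 at least 9.08-fold higher at 400 nM. Of the differences between the lines 2 rest on 1 group under that intensity, SJSA-1 with THZ2, those of ST6GALNAC5 at 25 nM and of ZNF518B at 100 nM.

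Across genes the log2 changes of the 2 lines had a Pearson r of 0.393 at 25 nM, 0.769 at 100 nM and 0.741 at 400 nM, with a Spearman rho of 0.263, 0.708 and 0.602. Genes are not independent replicates, so no p-value goes with these. At 100 nM 2701 genes fell in both lines against 891.1 by chance, 1671 rose in both against 783.2, and 111 moved in opposite directions. Falls of at least 2-fold were shared by 416 genes against 38.5 by chance. The lines do not share DMSO arrays.

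Untreated, SJSA-1 and U2-OS differed in 13744 genes, 3490 higher and 10254 lower in SJSA-1, a comparison across normalization sets. MDM2 and CDK4, which lie in the region that SJSA-1 is known to carry in extra copies, were higher in SJSA-1 by 3.03 ± 0.18 and 2.61 ± 0.059, with CDK4 at an intensity of 7556 ± 628 against 1218 ± 17.2. MYC was lower in SJSA-1, with a difference of -4.03 ± 0.10. MAGEA4 and CCND2 lay under the filter intensity of 12.73 in SJSA-1, at least 171-fold and 103-fold lower than their 2176 ± 122 and 1307 ± 47.0 in U2-OS. BASP1 and UCHL1 lay under it in U2-OS, and their 4445 ± 229.9 and 3545 ± 211 in SJSA-1 were at least 349-fold and 278-fold higher. CXCL8 differed by 5.34 ± 0.083. The split was 6695 higher and 5446 lower with median-centred arrays, 4403 and 7945 with quantile normalization, 1980 and 12560 with ribosomal centring, and 331 and 14191 with spike-in centring.

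Intensities of marker genes of other tissues, with DMSO in U2-OS and in SJSA-1, had medians of 29.8 and 18.8 over 15 nervous tissue markers, 18.8 and 11.3 over 10 blood and immune markers and 28.6 and 18.1 over 12 epithelial markers, against 55.4 and 36.5 over all 18132 genes. The highest of each list, named after the values were seen, were NEFL at 418 in U2-OS and SYP at 57.3 in SJSA-1, HBB at 73.9 and 48.2, and KRT18 at 2114 and 2597. These levels set no limit on a small share of other RNA. Of 12 tested nervous tissue markers 2 rose in SJSA-1 at 100 nM and 1 fell, of 12 epithelial markers 4 rose and of 8 blood and immune markers 3 rose, the same adjusted over each list alone and none with a called shift. The medians at 100 nM were 0.11, 0.15 and 0.13, and each turned negative with spike-in centring.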

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

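The tests of the 3 counts of line differences against other splits, and those on the small rises, the NF-kB target genes and the small RNAs other than the one on the median of their host genes, were chosen only after the result was seen.

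The lines differed in the effect of THZ2 for 174 genes at 25 nM, 2708 at 100 nM and 7385 at 400 nM, by a test of the difference itself. A first version of the split test left the effect common to both lines in the values, so that it did not test the difference, and 10, 11 and 6 of 100 drawn splits then gave as many genes, at most 990, 5574 and 10145. After that was seen the test was revised to take the common effect out first. In the revised test 1 of 100 splits, the real one, gave as many genes at each dose, which excludes chance as the source of these counts only as far as a test revised in this way can. The highest other counts were 9, 1986 and 4819, so at 100 and 400 nM other splits also called many genes. At 400 nM the U2-OS normalization set stays in the difference.

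For the counts within a line and for the DMSO groups 3 against 3 arrays give 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, gave its count. The real and the highest other counts were 13 and 0 for U2-OS at 25 nM, 6773 and 0 at 100 nM, and 11833 and 0 at 400 nM. In SJSA-1 they were 1322 and 466 at 25 nM, 7990 and 1 at 100 nM, and 10747 and 1064 at 400 nM. The dose steps gave 7757 and 0, and 10423 and 3, in U2-OS, and 6726 and 1, and 4281 and 4, in SJSA-1. The DMSO groups gave 13744 and 0. For the 58 list shifts 30 of 100 relabellings of the 12 arrays within each line gave as many, at most 87, so this test does not exclude chance. Such relabellings keep part of the drug effect.

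Lists whose effect differed between the lines by limma camera had these median differences, SJSA-1 minus U2-OS. At 25 nM they were 0.12 for immediate early genes, -0.15 for homologous recombination and checkpoint genes, -0.10 for S phase genes and -0.21 for NF-kB target genes. At 100 nM they were -0.33 for p53 target genes, 0.14 for histones, -0.067 for S phase genes, -0.25 for mitotic genes, -0.66 for NF-kB target genes and -0.10 for splicing factors. At 400 nM they were -1.20 for immediate early genes, -0.63 for p53 target genes, 0.020 for ribosomal proteins, -0.52 for mitotic genes, -0.70 for NF-kB target genes and 0.036 for KRAB-type zinc finger genes, where the medians of the ribosomal proteins and zinc finger genes turned negative with spike-in and with ribosomal centring. With an estimated correlation only the NF-kB target genes at 100 nM passed among these, at adjusted p = 0.0153.

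Single genes also differed between the lines by limma. SJSA-1 with THZ2 lay under the filter intensity for ST6GALNAC5 at 25 nM and ZNF518B at 100 nM. The scale sets part of the other ST6GALNAC5 values and of that of MYC at 400 nM. At 25 nM the differences were -0.92 for ARHGEF39, -0.95 for LIAT1, -1.07 for NABP1, -1.43 for ST6GALNAC5, 1.02 for SNORA26, 1.17 for SNORA3B and 0.97 for USP45. At 100 nM they were -2.55 for CXCL8, -2.43 for IGF2BP1, -2.40 for NFKBIZ, -2.39 for PHLDA1, -0.95 for CDK12, -0.89 for MCL1, -0.69 for CDK7 and -0.44 for CDKN1A. On the other side were 2.19 for ST6GALNAC5, 1.93 for ZNF518B, 1.81 for MYC and 0.41 for MNAT1. At 400 nM they were -3.55 for NFKBIZ, -3.23 for CXCL8, -3.18 for PHLDA1 and -2.63 for MCL1, and 3.17 for ST6GALNAC5, 2.12 for SCG5 and 2.07 for MYC.

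The poly-A spike-ins, which no comparison uses, were higher than in every DMSO array in all 3 arrays of U2-OS at 100 nM (mean change 0.38), of U2-OS at 400 nM (0.33) and of SJSA-1 at 100 nM (0.45). The hybridization controls, added after labelling, changed by 0.13, 0.49 and 0.12 in the same groups. In SJSA-1 at 400 nM the mean change was 0.97 but only 2 of 3 arrays exceeded the DMSO arrays.

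Many small rises stood beside large falls at 100 nM. Background of dim probe sets as the whole cause is argued against, since of the 4043 brightest genes 28.7% rose in SJSA-1 and 16.8% in U2-OS. Scaling of arrays after a loss of mRNA may be at work, since the poly-A spike-ins rose 0.33 more than the hybridization controls in SJSA-1 and 0.25 more in U2-OS. If added per mass of RNA, the spike-ins would read the share of mRNA in it, and only if per cell the mRNA per cell. The sources do not say which. A real increase stays open, since 17.9% of the risen genes were still above 0 with spike-in centring, and 98.2% if the shift is taken smaller by 1 SD of the spike-ins over the DMSO arrays.

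The NF-kB target genes responded differently in the lines at 100 nM. Separate normalization of the lines as the whole source is argued against, as far as a joint normalization can undo it, since with all arrays quantile normalized together the median difference was -0.74 (-0.97 to -0.25 over resampled members), with limma camera adjusted p = 6.86e-15 and adjusted p = 0.00224 with an estimated correlation. A higher starting level in SJSA-1 stays open. The members not higher there with DMSO, 5 to 12 depending on the scaling, had median differences of -0.77 to -0.62. Each lay under its random lists, which goes against it. Yet with each scaling their range over resampled members reached into that of random lists, with median centring -1.02 to 0.085 against -0.31 to 0.34. Such ranges cannot exclude it. A difference between the cell lines themselves stays open and was not tested, since the series holds 2 lines.

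Of small nucleolar and Cajal body RNAs, a set of 39 chosen after the values were seen, 26 rose and 0 fell in SJSA-1 at 100 nM by limma, with a median of 0.46. In 35 pairs members exceeded their hosts by 0.64 in the median (0.22 to 0.96 over resampled hosts), so in the median these hosts did not rise by as much. The set was chosen for rises of its members and not of its hosts, which favours such an excess. The value therefore describes these pairs and is no independent test. Random lists of like intensity had medians of 0.0029 to 0.12, though this set was chosen for its rises, and its median was 0.64 with median centring and 0.47 with quantile normalization. Whether the members rose, or were lifted with the arrays while other genes fell, stays open, since the median became 0.0033 with spike-in centring, where the SD of the spike-ins over the DMSO arrays was 0.34. Whether the host genes rose at all stays open, with a median of 0.023 over 31 hosts inside the -0.12 to 0.14 of random lists. A shift toward transcripts without poly-A tails stays undecided. Histone medians were 0.24 in SJSA-1, above random lists, and 0.11 in U2-OS, within them. They cannot decide it, since whether RNA without tails was labelled was not tested.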

How the results depend on the processing

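The fits without a pseudocount and on the arrays of 1 normalization run were chosen only after the result was seen. Of 267 results on named genes 205 kept their call and direction under the alternatives run for them, which leave out the pseudocounts of 1 and 64 and each probe set by itself, with 201 covered by the fit on 1 normalization run and 266 by the filter at the 50th percentile. Calls of named genes were lost in 47 with spike-in centring, 12 with the mean of probe sets, 5 with no pseudocount, 4 with median centring, 2 each on the groups of the comparison and on the normalization run, and 1 each with ribosomal centring and no intensity trend. Pearson r between the lines moved by less than its jackknife error with quantile normalization, 2 filters, the mean of probe sets, no pseudocount and any 1 array left out, and centring cannot move it. The cause of each change below was not tested. With spike-in centring the counts of changed genes became 0 for U2-OS at 25 nM, 3076 at 100 nM and 3501 at 400 nM, 2889 and 2329 for the U2-OS steps, 7 for SJSA-1 at 25 nM, 4165 at 100 nM, 3295 and 2150 for the SJSA-1 steps, and 0 and 49 for the line differences at 25 and 100 nM. The log2 changes of CDK12 (U2-OS, 100 nM), NDUFA12 (SJSA-1, 100 nM) and UQCRB (SJSA-1, 400 nM) turned to -0.045, -0.055 and -0.27 with it. With median-centred arrays 11544 genes changed in U2-OS at 100 nM, 13270 in SJSA-1 at 100 nM and 12612 in SJSA-1 from 25 to 100 nM. Quantile normalization gave 99 for the line difference at 25 nM, each probe set by itself 275, and no pseudocount 105. For U2-OS at 25 nM each probe set by itself gave 21 genes, no intensity trend 20, pseudocount 1 gave 4, pseudocount 64 gave 40 and no pseudocount 4. On the groups of the comparison alone the counts were 800 for U2-OS at 25 nM, 543 for SJSA-1 at 25 nM and 2301 for SJSA-1 from 100 to 400 nM, and on the normalization run 303, 559 and 2685, and 10229 for U2-OS at 100 nM. Counts of genes changed at least 2-fold, for U2-OS at 25, 100 and 400 nM and then SJSA-1 at these doses, were 0, 693, 1557, 11, 1044 and 1371. They became 1, 1054, 2515, 43, 1573 and 1914 with no pseudocount, 1, 1016, 2379, 40, 1522 and 1868 with pseudocount 1, 0, 297, 811, 1, 425 and 685 with pseudocount 64, 0, 310, 920, 7, 570 and 903 with the mean of a gene's probe sets and 0, 1584, 1960, 7, 2302 and 5291 with spike-in centring, and each probe set by itself gave 25 for SJSA-1 at 25 nM. For the steps from 25 to 100 nM in U2-OS and SJSA-1, that from 100 to 400 nM in SJSA-1 and the line difference at 100 nM they were 666, 771, 432 and 222, and became 988, 1296, 720 and 494 with no pseudocount, 268, 247, 173 and 67 with pseudocount 64, 297, 379, 254 and 119 with the mean of probe sets and 1478, 1718, 1072 and 49 with spike-in centring. Same-numbered arrays correlated in their deviations over 0.1 in 9 of 18 pairs in U2-OS and 8 of 18 in SJSA-1, and 8 of 12 and 3 of 12 arrays lay closest to an array of their own number, which is a hint of pairing in U2-OS only. Since not every pair was over 0.1, the numbers were not taken as pairing the samples. With the replicate number as a block all 14 counts stayed within 1.5 times their value. The block moved to the other side of the threshold EGR1 (-0.57, adjusted p = 0.0611), ASF1B (-0.45, adjusted p = 0.0611) and ZNF552 (0.29, adjusted p = 0.0878) in U2-OS at 25 nM, CDKN1A in SJSA-1 at 400 nM (-0.22, adjusted p = 0.0228) and the S phase genes in U2-OS at 400 nM (-0.18, adjusted p = 0.0511), and no other named gene or list. With an estimated correlation 5 of the 58 list shifts were called, and 34 of the 58 held under all others run for the lists, with the same left out. Calls ended for 19 lists with the filter at the 50th percentile, 11 with the mean of probe sets, 10 with quantile normalization, 9 with spike-in centring, 7 with fry, 6 with ribosomal centring, 5 with no intensity trend, 4 each with no pseudocount and on the groups of the comparison, 3 on the normalization run, 2 with median centring and 1 with no filter. Leaving out 1 array gave 4 to 8 genes for U2-OS at 25 nM, lowest without U2-OS DMSO replicate 1 and highest without U2-OS 25 nM replicate 1, and 79 to 320 for the line difference at 25 nM, lowest without U2-OS 25 nM replicate 3 and highest without SJSA-1 DMSO replicate 1. Lists not called with all arrays were called in SJSA-1 at 100 nM for YAP and TEAD targets without DMSO replicate 3 (-0.30) or 100 nM replicate 2 (-0.26) and ribosomal proteins without DMSO replicate 3 (0.048), at 25 nM for S phase genes without DMSO replicate 3 (-0.067), 25 nM replicate 1 (-0.095) or 3 (-0.059), histones without DMSO replicate 2 (0.047) and oxidative phosphorylation without DMSO replicate 3 (0.066), and at 400 nM for antiapoptotic genes without 400 nM replicate 2 (-0.26). In U2-OS this held at 100 nM for histones without 100 nM replicate 1 (0.11) and blood markers without 100 nM replicate 3 (0.16), and at 25 nM for S phase genes without DMSO replicate 2 (0.047), oxidative phosphorylation without 25 nM replicate 1 (0.024) and zinc finger genes without 25 nM replicate 1 (0.021).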

Other observations

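The follow-up of small nucleolar and Cajal body RNAs was chosen only after the result was seen. Of the 39 members 16 rose and 1 fell by limma in U2-OS at 100 nM, with a median of 0.14, which became -0.24 with spike-in centring. In SJSA-1 7 rose at 25 nM (median 0.12), and 28 rose and 1 fell at 400 nM (median 0.28, or -0.68 with spike-in centring). At 400 nM in U2-OS 27 rose and 3 fell, across normalization sets. The effect of 100 nM was higher in SJSA-1 than in U2-OS for 17 members and lower for 0, with a median difference of 0.27. Of the 31 host genes 8 rose and 9 fell in SJSA-1 at 100 nM, and the Spearman rho of member and host was 0.199 over 35 pairs, which are not independent replicates. Hosts were found by containment without regard to strand.

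In SJSA-1 the DMSO arrays spread more than those of U2-OS, with an SD of the mean poly-A spike-in level of 0.34 against 0.022.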
